A study of Drosophila melanogaster with 4 samples.

How the data were processed

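Small RNAs from Drosophila melanogaster ovaries were sequenced in 4 libraries. 2 libraries came from flies with germline knockdown of Ars2 (hairpin stock 106344 of the Vienna collection, called Ars2KD here) and 2 from flies with germline knockdown of the eye-colour gene white (stock 30033, the control, called wKD). Per the labels, total RNA was size-selected on a gel at 19 to 29 nt before library construction. Sequencing depth was not given in the sources used here, so the totals of the 2 tables stand in for it. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

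The authors deposited raw counts in 2 tables, which were used without change. The first holds counts for 495 mature miRNA loci under 469 names, of which 9 names occur at several loci. The second holds counts of reads of 24 to 29 nt, the length range of most Drosophila piRNAs, per the file headers, for 137555 annotated repeat copies. Of these copies, 40492 belong to 167 named transposon or satellite families, 97061 are simple or low-complexity repeats, and 15164 had a count in any library. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, featureCounts and the dm6 build. Versions, mapping settings, the handling of reads with several positions, and strand were not given in the sources used here. A read from a near-identical copy may therefore have been counted at another copy, and counts of single copies and of similar families are uncertain to that extent. Among all copies, 8454 overlap the copy before them, and sense and antisense reads could not be separated. Reads of 24 to 29 nt over a repeat were not otherwise checked to be piRNAs.

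Coordinates are 1-based dm6 positions from the tables. The Ensembl BDGP6 annotation of the same assembly was used for genes. Of the 481 miRNA loci on the main chromosomes, 479 had exactly the coordinates of an annotated mature miRNA. Repbase family names are those of the table, with internal and LTR parts summed to 1 family, and common names were added where overlap with annotated insertions or established usage gives them. Number of table columns not used: 0.

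Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling within each table, low counts removed by filterByExpr with the group given, no replicate block, Benjamini-Hochberg adjustment, adjusted p under 0.05). It was run on miRNA loci, on repeat copies, on counts summed per family, and on counts summed over fixed piRNA clusters and over the outermost 50 kb of chromosome arms. The regions were fitted together with all copies outside them. Normalised read counts are CPM after TMM scaling, and scaled values of the most abundant miRNA in Ars2KD 2 add up to more than the scale itself, because a few miRNAs held most of its counts. Values are mean ± SD with n = 2 per group. The total of 24 to 29 nt counts over the total of miRNA counts was compared by a two-sided exact permutation test on its log2. Lists of miRNAs and families were tested with limma 3.58.1 (camera with a preset correlation of 0.01 and again with an estimated correlation, and fry) on log2 CPM with a prior count of 2.

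Each ratio is also given between the libraries numbered 1 and between those numbered 2, with the exact 95% binomial interval of the counts. These intervals, and the floor of 3 counts per library used where a count was 0, cover counting error only, since reads without molecular identifiers are not independent molecules. Fold values against the floor leave out the counting error of the other library and are not bounds. The floor equals 64.9, 17.7, 46.6 and 9.28 CPM before TMM scaling in the repeat table and 4.59, 0.815, 2.84 and 0.659 CPM in the miRNA table, for Ars2KD 1, Ars2KD 2, wKD 1 and wKD 2. A chi-square check of all 6 pairs of libraries, in the miRNA and family counts, showed that no library repeats another. Python steps used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

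The tests, the lists, the regions and the rule for named items were fixed before the data were examined. The rule named, for each direction, items past the threshold whose groups did not overlap (up to 12 miRNAs, 10 families or 5 copies), filled to 6 miRNAs or families and 5 copies by lowest p with a mean of at least 10 CPM, plus the 10 most abundant miRNAs and families, every telomeric element, every region, and the most and least changed member of any list. Copies closer than 5 kb counted as 1 place. Items named outside it are said to be chosen after their values were seen. One entry of the germline list matched both BATUMI and Copia2. The miRNA lists were mirtrons, germline and maternal, ovarian somatic, muscle, neural, testis-biased, the mir-309 and mir-310 clusters, the mir-2 and mir-13 family (with mir-6, mir-11 and mir-308), the let-7 complex, mir-275 with mir-305, mir-277 with mir-34 and mir-317, the mir-9 family (with mir-79 and mir-306 of its cluster), mir-279 with mir-996 (and mir-286, which the mir-309 cluster also holds), mir-281, and 5p and 3p arms. The family lists were telomeric, germline-dominant, somatic follicle cell, both compartments, DNA transposons, and satellite or rDNA repeats.

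The fits were tested on simulated data, 10 simulations per table, with 200 changed copies or 30 changed miRNAs or families. With the spread seen between these libraries and a split by replicate number, the main test recovered 21.1%, 72.6% and 91.1% of families changed 2-, 4- and 8-fold (132 families) and 0% of copies (1420 copies) and of miRNAs (144 miRNAs) at each fold. Without the split it recovered 29.8%, 80.9% and 97% of families (130 families), 0.366%, 7.99% and 23.6% of copies (1348 copies) and 0% of miRNAs (132 miRNAs). The fit with the replicate number as a block, on the data simulated with the split, recovered 75.6%, 94.1% and 97.8% of families, 8.73%, 50.2% and 85.8% of copies and 3.37%, 13.1% and 28.3% of miRNAs, with 2.99%, 2.53% and 6.67% of its calls false. With a small dispersion of 0.05, a setting added after the miRNA result above was seen, the main test recovered 35.4%, 96% and 98.9% of miRNAs (140 miRNAs). In 50 simulations of 133 families, camera found a list of 10 families shifted 2-fold in 100% and an unshifted list in 2%. These used the smaller spread of the block fit, no split by number, members drawn independently and an unadjusted p under 0.05. They were easier than the list tests reported below, so these rates do not carry over to them.

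Alternatives tried were DESeq2 size factors, scaling to the total of both tables, to the table's own total and, for repeats, to the miRNA total, no filter on low counts, DESeq2 1.42.0, limma-voom, a replicate block, copies of at least 1 CPM only, totals without the 10 most abundant items, an estimated correlation in the list tests, and each library left out. A family fit without the copies of 1 place on 2L was chosen after seeing the data. Not tested for low counts were TART-B1, Juan, Transpac and the 2 BARI families, cluster 20A and the X end. Ars2 and white transcripts were not analysed here, so the knockdown itself was not checked.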

Results

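The ovary data comprised 2 Ars2KD and 2 wKD small RNA libraries. Ars2 is an RNA-binding protein that acts with the nuclear cap-binding complex, and the series title gives its role in silencing telomeric repeats and transposons as the subject. The miRNA counts were 653566 and 3681482 in Ars2KD 1 and 2, and 1056475 and 4554667 in wKD 1 and 2. Counts of 24 to 29 nt reads over repeats were 46218 and 169124 in Ars2KD and 64395 and 323180 in wKD. In every library LINE and LTR retrotransposons held most repeat counts, with mean shares of 42.2% and 46.7% in Ars2KD and 41.5% and 46.2% in wKD. Across 152 miRNAs the log2 CPM correlated with r = 0.98 and 0.96 between groups at numbers 1 and 2, against 0.71 within Ars2KD and 0.74 within wKD. Across 133 families these values were 0.963 and 0.966, against 0.943 and 0.964, a small difference in this measure. The split was not confined to miRNAs, however. Deviations from the group means correlated between same-numbered libraries by 0.69 over families and 0.90 over miRNAs. Ratios are given pooled and also within number 1 and number 2, in that order.

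The first comparison asked which miRNAs differed in abundance between Ars2KD and wKD ovaries. The miRNA profile was dominated by miR-184-3p, a maternally loaded miRNA (2R:13329420-13329441, exon of lncRNA:CR44206), which took 47.6% of miRNA counts in Ars2KD 2 and 35.1% in wKD 2. Its normalised count was 794131 ± 1046690 CPM in Ars2KD and 292336 ± 339643 CPM in wKD (SD, n = 2), a log2 ratio of 1.44 (SE 2.21), with 0.05 and 1.53 within numbers. The TMM factors for miRNAs were 2.22 and 0.310 in Ars2KD 1 and 2 and 2.21 and 0.658 in wKD 1 and 2. The low factor of Ars2KD 2 raised every miRNA ratio within number 2 above the ratio of count shares. Part of each rise within number 2 therefore comes from scaling. bantam-3p, a growth-promoting miRNA (3L:642259-642281), had a log2 ratio of 0.08 (SE 1.74; 0.11 and 0.07 within numbers), and its sign turned under DESeq2 size factors (-0.03) and scaling to table totals (-0.38 and -0.39). The follicle cell miRNAs miR-989-3p and miR-994-5p had log2 ratios of 1.10 (SE 1.87; 0.12 and 1.27) and 0.21 (SE 1.56; 0.35 and 0.03). In Ars2KD 1 the top miRNA was miR-8-3p with 15.4% of counts, and in wKD 1 it was miR-12-5p with 12.9%.

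No miRNA passed the edgeR test: 0 of 152 were higher and 0 lower, all those named had an adjusted p of 0.997, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The higher miRNAs with the lowest p included miR-281-1-5p (2R:12170427-12170449, exon of asRNA:CR46194 and intron of Oda), at 497 ± 633 against 82.8 ± 85.7 CPM, a log2 ratio of 2.58 (SE 1.98; 1.16 and 2.72 within numbers). miR-13b-2-5p, from an intron of CCT2 (X:9091237-9091260), had 1.65 (SE 1.59; 0.09 and 2.87). miR-14-5p, whose hairpin also gives the cell-death regulator miR-14 (2R:9553765-9553786), had 2.33 (SE 2.34; 0.20 and 2.40). The others were miR-5-5p at 1.74 (SE 1.88), miR-313-5p at 1.45 (SE 1.61) and miR-284-5p, within the 3' UTR of Octbeta2R, at 1.58 (SE 1.91). On the lower side, miR-304-5p, from an intron of Gmap (X:15508970-15508992), had 2088 ± 2896 against 12250 ± 17279 CPM, a log2 ratio of -2.55 (SE 2.82), with -2.56 and 0.36 within numbers. miR-311-3p and miR-312-3p of the mir-310 cluster had -1.61 (SE 1.61; -0.05 and -2.70) and -1.29 (SE 1.88; 0.41 and -1.55), and miR-991-3p of the same cluster had -1.44 (SE 2.02). miR-318-3p, a follicle cell miRNA, had -1.12 (SE 1.77; -0.15 and -1.31), and miR-87-3p had -1.07 (SE 1.76; -1.46 and 0.14). Among the other abundant miRNAs, miR-263a-5p had 1.26 (SE 2.32), miR-92b-3p 0.66 (SE 2.29; -0.45 and 0.69, turning to -0.38 and -0.41 under scaling to table totals), miR-12-5p -0.25 (SE 1.63) and miR-8-3p 0.17 (SE 1.67; 0.63 and -0.98, turning to -0.18 with limma-voom). Every Ars2KD library lay above every wKD library for 3 of 152 miRNAs and below for 2, where chance gives 33.3% for both directions together. That share assumes libraries that could be exchanged, which the split by number goes against.

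The edgeR test, which has no term for the replicate number, recovered 0% of simulated 8-fold changes at this spread, and 11 of the 20 named miRNAs reversed without Ars2KD 2. For example, miR-14-5p went to -2.76 and miR-184-3p to -2.44 without that library.

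**Figure D1:**
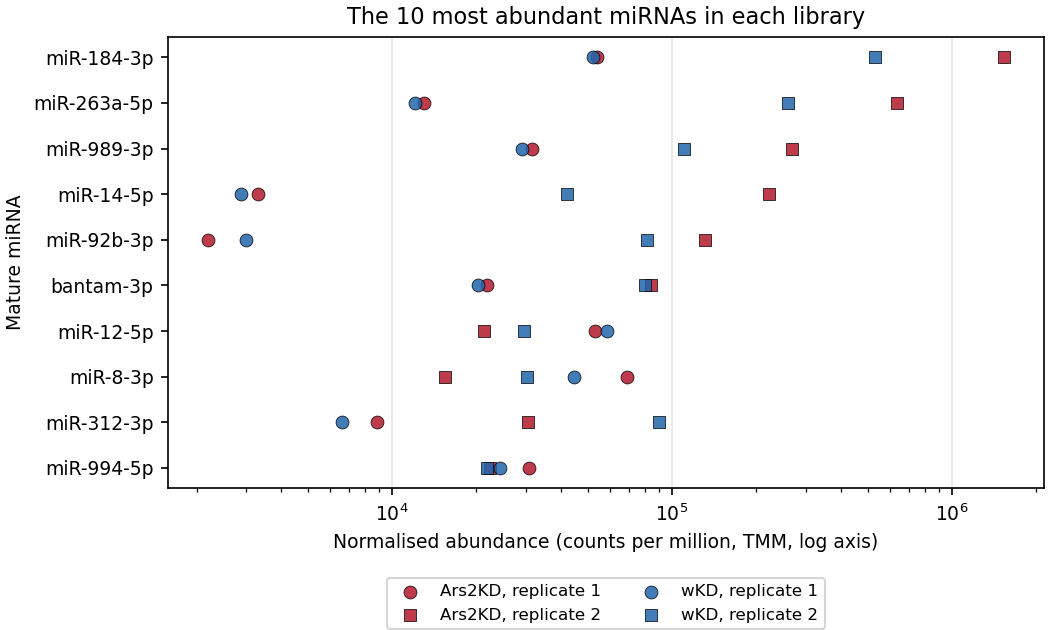
Normalised counts (CPM, log axis) of the 10 most abundant miRNAs, with 1 point per library, colours for the groups, circles for libraries numbered 1 and squares for those numbered 2. For miR-184-3p the 2 circles lie at 54011 (Ars2KD) and 52172 (wKD) CPM and the 2 squares at 1534250 and 532500 CPM.

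The fixed miRNA lists asked whether related miRNAs moved together. No list passed camera after adjustment, and the lowest adjusted p, 0.184, belonged to the mir-310 cluster and to the mir-2 and mir-13 family. The mir-310 cluster, which is maternally expressed, had a median log2 ratio of -0.58 (3 of 9 members above 0, from miR-311-3p at -1.61 to miR-313-5p at 1.45), and the mir-2 and mir-13 family, whose members include apoptosis regulators, had 0.49 (7 of 11). Scaling to the total of both tables brought the mir-310 cluster past the threshold (adjusted p 0.0466, but adjusted p = 0.986 with an estimated correlation; the preset-correlation range over its alternatives was 0.0466 to 0.995). Mirtrons, which are made by splicing instead of Drosha, had a median of -0.44, with 1 of 7 above 0 (adjusted p 0.359), between miR-1003-3p at -1.61 and miR-1012-3p at 0.74. Their median went to -4.88 without Ars2KD 1 (0 of 7 above 0), to 1.95 without wKD 1 (5 of 6) and to 0.05 without Ars2KD 2 (5 of 7), so its direction rested on single libraries. Medians were -0.02 for ovarian somatic miRNAs (14 members, from miR-318-3p to miR-989-3p), 0.08 for neural miRNAs (4), -0.02 for the let-7 complex (6) and 0.52 for mir-277 with mir-34 (6). Those that turned below 0 under scaling to the total of both tables were 0.03 for germline and maternal miRNAs (19), 0.06 for testis-biased miRNAs (9), 0.16 for mir-275 with mir-305 (4), 0.01 for the mir-9 family (9), 0.07 for mir-279 with mir-996 and mir-286 (5), 0.07 for 5p arms (82) and 0.05 for 3p arms (70). The germline and mir-9 medians also turned, to -0.01, under DESeq2 size factors. With 1 library left out, only the mir-310 cluster (-0.87 to -0.22) and the mir-2 and mir-13 family (0.05 to 0.59) kept the sign of their median. The others ranged from -1.22 to 0.40 (ovarian somatic), -0.91 to 0.51 (neural), -1.25 to 0.41 (let-7), -2.01 to 1.65 (mir-277 with mir-34), -0.52 to -0.18 (germline and maternal), -0.19 to 0.52 (testis), -0.13 to 0.77 (mir-275 with mir-305), -0.24 to 0.41 (mir-9), -2.31 to 2.71 (mir-279 with mir-996), -0.13 to 0.29 (5p arms) and -1.43 to 0.65 (3p arms). Median and camera direction differed in sign for the germline, 3p, mir-9, neural and testis lists, and median and mean differed for the germline, 3p, mir-9, let-7 and mir-279 lists. Muscle miRNAs (0.74), the mir-309 cluster (1.13) and mir-281 (1.87) had 2 tested members each and no list test, and without Ars2KD 2 their medians were -0.39, -1.36 and -1.94. In each list 0 members were past the threshold adjusted over the list alone, and 0 over all miRNAs. The 5p and 3p lists split all tested miRNAs between them, so a call of both is 1 result. Without Ars2KD 1, camera called both arm lists, with an adjusted p of 0.0469 for each (adjusted p = 0.791 with an estimated correlation).

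The comparison of 24 to 29 nt reads per transposon family asked which elements gained or lost small RNAs. Reads over jockey, a non-LTR retrotransposon (LINEJ1_DM in the table), rose from 2025 ± 370 CPM in wKD to 11381 ± 290 CPM in Ars2KD (SD, n = 2), a log2 ratio of 2.48 (SE 0.32, edgeR adjusted p 0.000478), with 2.66 (95% interval 2.38 to 2.95) and 2.34 (2.21 to 2.47) within numbers. HeT-A, the main telomeric retrotransposon, had 3669 ± 228 CPM in Ars2KD and 9055 ± 1209 CPM in wKD, a log2 ratio of -1.30 (SE 0.30), with -1.37 (-1.61 to -1.14) and -1.22 (-1.36 to -1.09) within numbers. HeT-A missed the threshold in the main test (adjusted p 0.0595) and passed with DESeq2 (0.00686) and limma-voom (0.0419), with a range of 3.53e-07 to 0.98 over its alternatives. The LTR retrotransposons copia and invader6 had -1.17 (SE 0.32, adjusted p 0.132; -1.40 and -0.87 within numbers) and -1.10 (SE 0.33, adjusted p 0.196; -0.70 and -1.60).

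In all, 1 of 133 families was higher and 0 were lower in edgeR, with 14 at an unadjusted p under 0.05 (6 higher, 8 lower). DESeq2 and limma-voom each called jockey higher and HeT-A lower, and edgeR without a filter called jockey higher and HeT-A, copia and invader6 lower (3). A single copy on 2L held 90.0% of the jockey difference, and without the copies of that place, an exclusion chosen after seeing the data, jockey had 0.56 (SE 0.275, adjusted p 0.419) and 0 families were higher. The other families of lowest p on the higher side were G5 at 0.85 (SE 0.27, adjusted p 0.214; 0.67 and 1.02 within numbers), R1-2 at 0.79 (SE 0.29), Ulysses at 1.37 (SE 0.58), Mariner2 at 1.02 (SE 0.44) and mdg3 at 0.69 (SE 0.31). Single copies on 3L and 3R held 89.1% of the Mariner2 difference and 88.2% of the mdg3 difference, and the other copies had 0.19 and 0.23 for Mariner2 and 0.08 and 0.12 for mdg3 within numbers. On the lower side, the Responder satellite of chromosome 2 had 142 ± 33.5 against 486 ± 248 CPM, a log2 ratio of -1.70 (SE 0.65, adjusted p 0.385), with -2.49 and -0.91 within numbers and 8 of 8 counted copies lower. The LTR elements opus (NOMAD in the table) and flea (BLASTOPIA) had -0.79 (SE 0.31; -0.77 and -0.80) and -0.74 (SE 0.29; -0.32 and -1.11). Single copies held 72.7%, 75.8% and 88.7% of the differences of copia, invader6 and flea, all on 2R within cluster 42AB, against 26.6% for HeT-A (4:1314345-1320140), whose counted copies were lower in 14 of 16 cases. The counted copies of HeT-A and of Responder are not replicates, and near-identical copies may share reads. Without Ars2KD 1, 2 families were higher (jockey and Doc2) and 1, invader6, was lower, and without wKD 2, 2 were higher (jockey and Stalker2).

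The telomeric list contained HeT-A, its partner TAHRE at -0.45 (SE 0.44, adjusted p 0.918; -0.38 and -0.51 within numbers), the subtelomeric repeat HETRP at -0.73 (SE 0.34; -0.79 and -0.70) and TART. TART had a pooled log2 ratio near 0 (adjusted p 0.995), at 999 ± 226 and 995 ± 113 CPM, with 0.11 and -0.12 within numbers, and the sign of its pooled ratio turned under DESeq2 size factors (0.01), its own table total (0.03) and without the 2L place (0.00). The list median was -0.59, and 0 of 4 members were above 0, with 1 of 4 above 0 under DESeq2 size factors. Camera gave an adjusted p of 0.0988, and adjusted p = 0.784 with an estimated correlation, and fry, which asks only whether the members move one way, gave an adjusted p of 0.00579. The fry result missed the threshold with scaling to the total of both tables (0.564) and without any 1 library (0.0774 and 0.149 without Ars2KD 1 and 2, 0.423 and 0.265 without wKD 1 and 2). Over all families 0 members were lower, and 1 was lower adjusted over the list alone. TART-B1 had counts of 3 and 6 in Ars2KD and 2 and 0 in wKD and was not tested.

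The germline-dominant list had a median of 0.01 over 32 families, with 16 above 0, from copia at -1.17 to jockey at 2.48 (camera adjusted p 0.681). Its median turned to -0.13 under scaling to the total of both tables, to -0.16 without Ars2KD 2 and to -0.01 without wKD 1. Over all families 1 member was higher, and 1 was higher and 1 lower adjusted over the list alone. The follicle cell list, which follows common usage as dominated by flamenco, had a median of -0.01 over 13 families. Its members ranged from ZAM at -0.43 (SE 0.29) to gypsy10 at 0.67 (SE 0.31), with a mean of 0.02. Past either adjustment were 0 members, and the list median turned to 0.03 without Ars2KD 1 and to 0.03 without wKD 1. DNA transposons had a median of -0.18 with 2 of 13 above 0 (adjusted p 0.159), from FB at -0.84 (SE 0.39) to transib3 at 0.12 (SE 1.25). That list passed without Ars2KD 1 (adjusted p 0.0253, but adjusted p = 0.906 with an estimated correlation), but its median turned to 0.02 without Ars2KD 2 (7 of 13 above 0) and was -0.05 without wKD 1 (6 of 13). Families of both compartments had -0.04 over 12, from opus to mdg3, and satellite or rDNA repeats had -0.10 over 4, from Responder to R2 at 0.24. In these 3 lists 0 members passed over all families and 0 adjusted over the list alone. Among the most abundant families, gypsy8 had 0.66 (SE 0.40; 0.52 and 0.76), Rt1b -0.30 (SE 0.48), BS -0.23 (SE 0.67), INE-1 -0.18 (SE 0.37) and roo 0.12 (SE 0.42; 0.51 and -0.47). A single copy at the 2L place (2L:23332648-23332738) held 47.6% of the gypsy8 difference, and without the copies of that place gypsy8 had 0.28 (SE 0.39). Single copies in 42AB held 96.2% of the Rt1b and 85.4% of the BS difference, and the other copies had 0.12 and -0.14 for Rt1b and -0.08 and -0.22 for BS within numbers. BATUMI had -0.08, Cr1a -0.08, Max -0.05, rooA 0.04 and Rt1a 0.02. The signs of rooA (-0.14) and Rt1a (-0.05) turned under scaling to the total of both tables. Groups did not overlap for 22 families higher and 23 lower of 133, where chance gives 33.3% for both directions together.

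**Figure D2:**
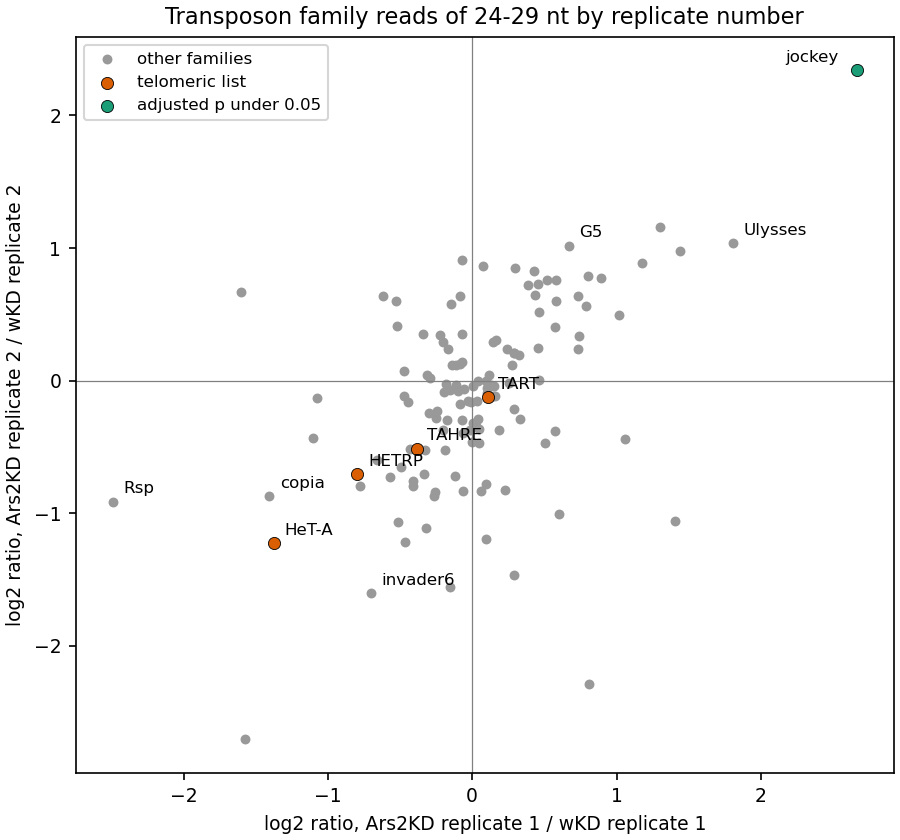
Log2 ratio of Ars2KD to wKD for 131 repeat families between libraries numbered 1 (x axis) and between libraries numbered 2 (y axis), with 1 point per family and colours for the telomeric list and for jockey, which passed the test. The jockey point lies apart at 2.66 and 2.34, HeT-A lies at -1.37 and -1.22, and 82 of 131 families had the same sign in both.

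The test on single copies asked where in the genome the reads differed. A jockey fragment in pericentromeric 2L (2L:23331997-23332192, between genes, 7805 bp from CR42530) rose from 2 and 11 counts in wKD 1 and 2 to 435 and 1316 in Ars2KD 1 and 2. Its normalised count was 8361 ± 158 CPM in Ars2KD and 33.6 ± 6.80 CPM in wKD (SD, n = 2), a log2 ratio of 7.86 (SE 0.63, edgeR adjusted p 0.00602), with 8.20 (6.34 to 11.25) and 7.75 (6.90 to 8.75) within numbers. Next to it, 3 gypsy8 fragments, chosen after their values were seen, brought the 4 copies of 2L:23331997-23332738 to 987 and 4747 counts in Ars2KD against 3 and 15 in wKD. The log2 ratios of these 4 copies together were 8.80 (7.25 to 11.08) and 9.15 (8.43 to 9.99).

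Of 1647 copies, 1 was higher and 0 were lower in edgeR, with 68 at an unadjusted p under 0.05 (35 higher, 33 lower). DESeq2 called 4 higher and 3 lower, limma-voom called 1 and 0, and the edgeR test without a filter called 4 and 4. Leaving out 1 library gave 4 higher copies for Ars2KD 1 and 3 for each of the others, among them the jockey fragment and 2 gypsy8 fragments beside it, and 5 lower copies without wKD 1. The other higher copies of lowest p were an mdg3 internal part in an intron of Myo81F (3R:2087179-2089038) at 4.96 (SE 0.73, adjusted p 0.0933; 46 and 263 against 3 and 11 counts), Gypsy1-I_DM at 3L:24563052-24563941 at 3.13 (SE 0.73), and 2 Rt1a copies (DMRT1A) at 3R:4045090-4045412 and 3L:23460583-23464807 at 3.11 (SE 0.75) and 2.22 (SE 0.55). On the lower side, an Invader1 internal part in 42AB (2R:6391465-6392463) had 0 and 0 counts in Ars2KD against 11 and 121 in wKD. Against a floor of 3 counts per library it was 2.71-fold and 22.5-fold lower within numbers 1 and 2. Its counting intervals reached up to log2 ratios of -0.89 and -4.17 within these numbers. An FB4_DM copy in an intron of SPoCk (3L:22751206-22751730) had 0 and 0 against 6 and 92 counts, 17.1-fold lower within number 2 against that floor. Its counting interval reached up to -3.77 within number 2. Within number 1 the interval reached 0.20 and so included no change. Gypsy12_I-int at 3R:3913867-3915014 had 13 and 18 against 105 and 406 counts, a log2 ratio of -3.05 (SE 0.67, adjusted p 0.565). PROTOP_B at 3R:3889314-3889839 had 0 and 2 against 18 and 45 counts. It was 4.44-fold lower against the floor within number 1, with an interval up to a log2 ratio of -1.70. Within number 2 its log2 ratio was -3.65 (-6.74 to -1.71). Gypsy9_I-int in an intron of Myo81F (3R:1160062-1161263) had 0 and 2 against 17 and 43 counts. It was 4.19-fold lower against the floor within number 1, with an interval up to a log2 ratio of -1.61. Within number 2 it had -3.58 (-6.67 to -1.64). Groups did not overlap for 280 copies higher and 279 lower of 1647, where chance gives 33.3% for both directions together.

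**Figure D3:**
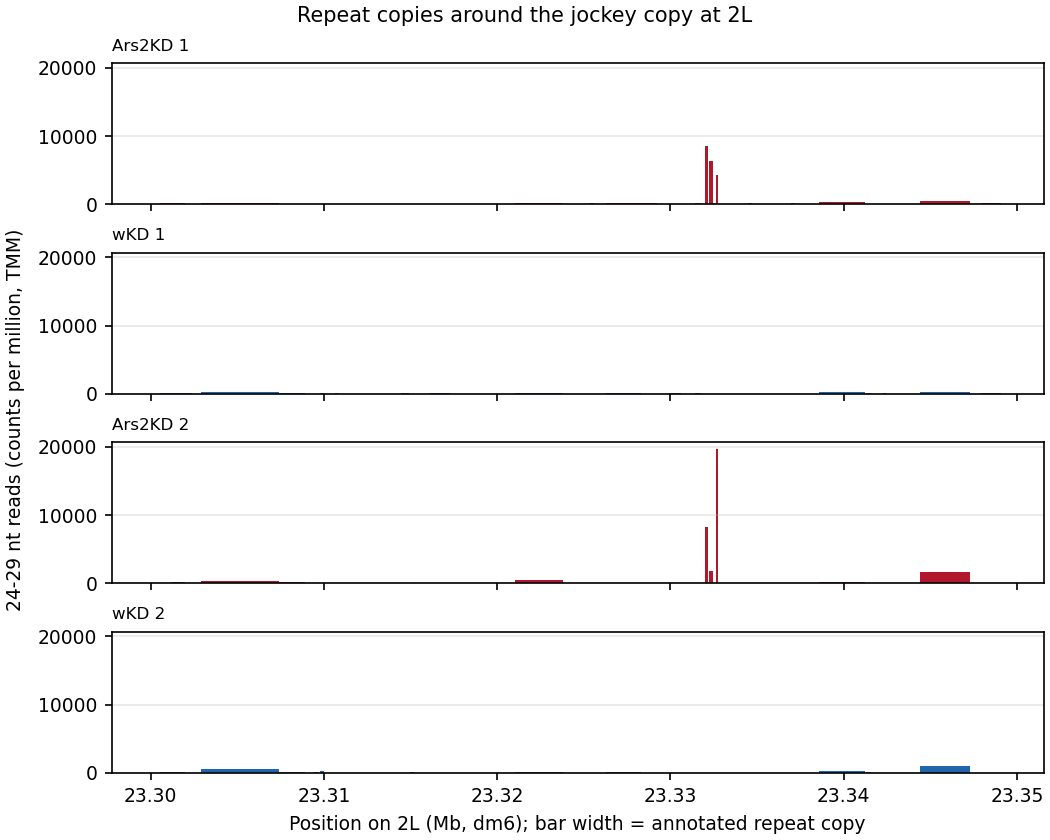
Normalised counts of 24 to 29 nt reads (CPM, linear axis) of the repeat copies around the jockey fragment against position on 2L (Mb, dm6), with 1 panel per library and bar widths equal to the annotated copies. Tall bars stand in both Ars2KD panels between 23331997 and 23332738, where 987 and 4747 counts fell in Ars2KD 1 and 2 and 3 and 15 in wKD 1 and 2.

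The region comparison asked whether reads from piRNA clusters and chromosome ends differed. Reads from the outermost 50 kb of chromosome 4, which hold HeT-A copies, were 866 ± 663 CPM in Ars2KD and 3444 ± 1858 CPM in wKD (SD, n = 2), a log2 ratio of -2.01 (SE 0.75), with -1.83 and -2.42 within numbers. The 2R end had 1250 ± 176 and 3086 ± 357 CPM, a log2 ratio of -1.30 (SE 0.55; -1.33 and -1.28). The HeT-A copy that added most to the family fall held 60.8% of the 4 end difference. A HeT-A copy held 41.8% of the 2R end difference. Without these copies the 4 end had -2.25 and -2.61 and the 2R end -1.57 and -0.98 within numbers. These ends and the HeT-A family share reads and are not separate results. The 3R end had -1.07 (SE 0.63; -1.56 and -0.76). Cluster 42AB, a major germline piRNA source, had -0.55 (SE 0.34; -0.48 and -0.59), with 20.3% and 27.2% of repeat counts in Ars2KD 1 and 2 and 25.9% and 36.0% in wKD 1 and 2. The somatic cluster flamenco had -0.18 (SE 0.37; -0.29 and -0.03).

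No region passed the edgeR test: 0 of 9 were higher and 0 lower, with 2 at an unadjusted p under 0.05, the 4 end (0.0246) and the 2R end (0.0413), both at an adjusted p of 0.186. DESeq2 also called 0, while limma-voom called these 2 lower. Leaving out Ars2KD 1 or wKD 2 made the 4 end pass, and leaving out wKD 1 made 42AB pass at -0.995. The 3L end had only 2 and 1 against 6 and 34 counts (-2.56, SE 1.49; -1.23 and -4.34), and the 2L end had -0.74 (SE 0.76; -0.52 and -1.03). Cluster 80F had -0.27 (SE 0.33) and 38C had 0.02 (SE 0.36), with 38C turning to -0.02 under scaling to the total of both tables and to -0.13 without a filter. Groups did not overlap for 0 regions higher and 5 lower of 9, where chance gives 33.3% for both directions together. The X end had 1 and 4 against 1 and 5 counts and 20A had 1 and 0 against 0 and 0, and neither was tested.

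**Figure D4:**
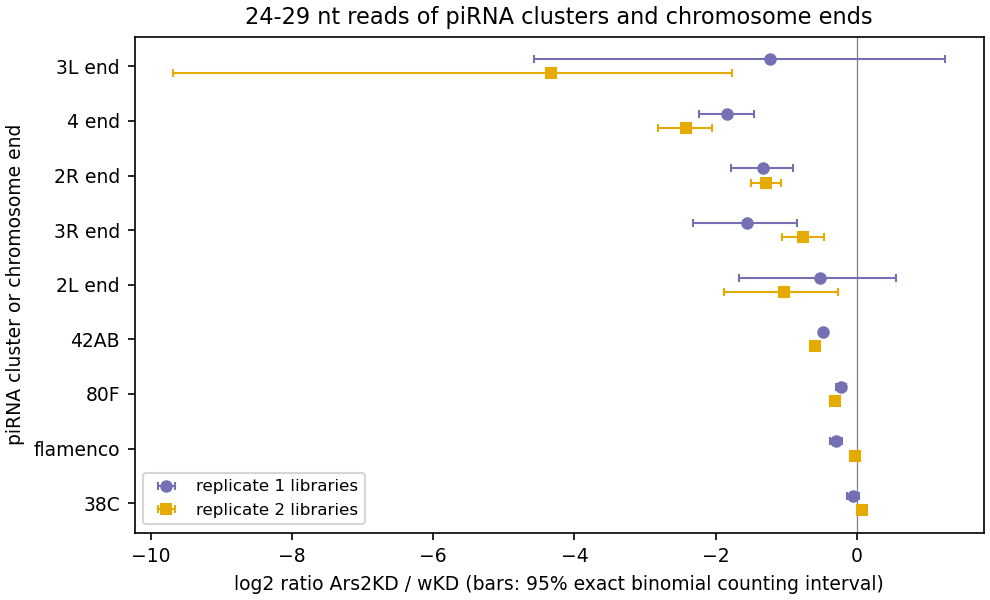
Log2 ratio of Ars2KD to wKD for 24 to 29 nt reads of each piRNA cluster and chromosome end (x axis), with circles for libraries numbered 1, squares for those numbered 2 and bars for the exact 95% binomial counting interval. The 4 end lies at -1.83 and -2.42 and the 2R end at -1.33 and -1.28, while 38C lies near 0 on both sides and its pooled sign turned under scaling to the total of both tables.

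The last comparison asked whether the amount of repeat reads relative to miRNAs differed between the groups. The 24 to 29 nt repeat total was 7.07% and 4.59% of the miRNA total in Ars2KD 1 and 2 and 6.10% and 7.10% in wKD 1 and 2. The means were 5.83 ± 1.75% and 6.595 ± 0.707% (SD, n = 2), a log2 difference of -0.21 (two-sided exact permutation p = 0.667, where the smallest this design allows is 0.333). Without the 10 most abundant items of each table the difference turned to 0.39, and without Ars2KD 2 it turned to 0.10.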

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

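Alternatives were set before the data were examined, except the fit without the copies of the 2L place, which was chosen after the result was seen. The cause was not tested for any change below unless one is named. The jockey family and the jockey copy stayed past the threshold in all 13 and all 12 alternatives fixed beforehand, with log2 ratios of 2.36 to 2.70 and 7.59 to 8.13. Without the 2L place 0 families were higher, by the construction of that setting. HeT-A kept its direction in 14 of 14 alternatives (-1.43 to -1.12) and was past the threshold in 4. Of the named comparisons, counted once per alternative, 306 of the family values kept direction and side of the threshold (18 gained the threshold, 1 lost it, 25 reversed), against 100 for copies (18 gained), 190 for miRNAs (30 reversed) and 101 for regions (9 gained, 5 reversed). Scaling moved the median of all miRNAs by -0.23 (total of both tables) and -0.24 (own total), of families by -0.14 (total of both tables, and miRNA total) and of copies by -0.11 (both of these). In Ars2KD 1 the floor of 3 counts equals 64.9 CPM for copies and families alike.

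Higher copies numbered 2 with scaling to the total of both tables, to the own total or to the miRNA total, and 4 with no filter or DESeq2, against 1. Lower copies numbered 4 with no filter and 3 with DESeq2, against 0. Lower families numbered 3 with no filter and 1 each with DESeq2 and limma-voom, against 0. Lower regions numbered 2 with limma-voom, against 0. One miRNA list (1), the mir-310 cluster, passed with scaling to the total of both tables, with an adjusted p of 0.986 with an estimated correlation. The difference of totals was 0.39 without the 10 most abundant items of each table.

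The replicate block gives 1 residual degree of freedom, and libraries share only a number, which the labels do not tie to a shared day. Same-numbered libraries deviated together (r = 0.90 for miRNAs, 0.69 for families, 0.61 for copies). With the replicate block 23 copies were higher and 46 lower, 14 families higher and 17 lower, 4 regions lower (the ends of 4, 2R and 3R, and cluster 42AB) and 0 miRNAs called. HeT-A, copia and invader6 were among the lower families, and fry gave the telomeric list an adjusted p of 0.106. By list, 4 germline-dominant families were higher and 5 lower, 2 follicle cell families higher and 0 lower, and 0 telomeric higher and 2 lower. For DNA transposons these counts were 0 and 3, for both compartments 1 and 1, and for satellite or rDNA repeats 0 and 1. The jockey copy and family were called in both fits. Medians turned below 0 for the germline (-0.30), 3p (-0.32), mir-9 (-0.30) and neural (-0.16) miRNA lists. The signs agreed for 1550 of 1647 copies, 127 of 133 families, 140 of 152 miRNAs and 9 of 9 regions.

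Reversed values were, for miR-92b-3p, -0.38 (total of both tables) and -0.41 (own total). For bantam-3p they were -0.029 (DESeq2 size factors, and DESeq2), -0.38 (total of both tables) and -0.39 (own total). For miR-8-3p they were -0.18 (limma-voom) and -0.17 (replicate block). TART reached 0.0064 (DESeq2 size factors), 0.0055 (DESeq2), 0.033 (own total) and 0.00156 (without the 2L place). Rt1a reached -0.053 (total of both tables), -0.0020 (no filter) and -0.057 (miRNA total), rooA -0.14 and -0.15 (total of both tables, and miRNA total), and cluster 38C -0.016 (total of both tables), -0.024 (miRNA total) and -0.13 (no filter).

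With 1 library left out, the lone library of a group is assumed to vary like the others. The 3L end (without Ars2KD 2 or wKD 2) and the FB4_DM and Invader1 copies (without wKD 2) fell below the count filter and have no value. The 2 miRNA arm lists split all tested miRNAs between them, so a call of both is 1 result. Counts were 3 to 4 higher and 0 to 5 lower for copies, 1 to 2 higher and 0 to 1 lower for families, 0 to 1 lower for regions, 0 to 2 miRNA lists and 0 to 1 family lists past the threshold. The lists passed without Ars2KD 1 (both arms of the miRNAs, and DNA transposons) had adjusted p values of 0.791, 0.791 and 0.906 with an estimated correlation. Leave-one-out log2 ranges of the miRNAs were miR-281-1-5p -0.74 to 4.27, miR-14-5p -2.76 to 5.07, miR-5-5p -0.23 to 2.81, miR-313-5p -0.085 to 2.09, miR-284-5p -1.58 to 3.23, miR-304-5p -8.33 to 6.11, miR-991-3p -2.63 to 0.48, miR-312-3p -2.45 to 1.39, miR-318-3p -2.29 to 0.84, miR-87-3p -1.94 to 0.68, miR-184-3p -2.44 to 3.72, miR-263a-5p -3.39 to 4.54, miR-989-3p -1.16 to 2.16, miR-92b-3p -4.27 to 4.26, bantam-3p -1.21 to 1.21, miR-12-5p -1.13 to 0.35, miR-8-3p -1.36 to 0.86 and miR-994-5p -0.12 to 0.40. Ranges of the families were TART -0.19 to 0.23, Rt1b -0.68 to 0.34, BATUMI -0.90 to 0.73, Rt1a -0.017 to 0.11, Cr1a -0.14 to 0.023, rooA -0.29 to 0.36, BS -1.60 to 1.15, roo -0.49 to 0.57, Max -0.13 to 0.059 and INE-1 -0.46 to 0.087. Cluster 38C ranged from -0.22 to 0.15 and the difference of totals from -0.52 to 0.10.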

Other observations

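In this part, the tests of a general jockey increase and of scaling for the 2L place, of scaling and of germline share for HeT-A, and of a library batch for miRNAs were chosen only after the results were seen. A stretch of 8 repeat copies in cluster 42AB, 2R:6384021-6392913, held 0 and 1 counts of 24 to 29 nt reads in Ars2KD 1 and 2 against 47 and 308 in wKD 1 and 2. It includes the Invader1 internal part named in the report, and it was picked after the values were seen, as were the bounds of the 2L place below. At the wKD rate 34.8 and 172 counts would fall in the Ars2KD libraries. Between libraries numbered 1 the stretch was 11.6-fold lower against a floor of 3 counts per library, without the counting error of wKD 1. Its log2 ratio between libraries numbered 2 was -7.42 (95% interval -12.73 to -4.93). The whole of cluster 42AB had -0.48 and -0.59 within numbers. On 2L, a Ulysses internal part about 4 kb beyond the jockey and gypsy8 fragments (2L:23336936-23337163) had 8 and 10 counts in Ars2KD and 0 and 0 in wKD.

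Arms of the same hairpin were compared in 52 miRNA hairpins, with the test chosen before its result was seen. The mean change in the log2 ratio of 5p to 3p arm in Ars2KD was -0.273 between libraries numbered 1 (20 of 52 above 0, sign-flip permutation p = 0.0257) and 0.42 between those numbered 2 (26 of 52, p = 0.166). The test needed a rise in both for a shift towards 5p arms and would have excluded a shift by 1 value at or below 0. That bound was wrong, since each p runs over hairpins within 1 pair of libraries and does not cover the spread between libraries, and the pairs went opposite ways. A shift in either direction stays open.

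At 2L:23331997-23332738 a jockey and 3 gypsy8 fragments carried reads in Ars2KD and almost none in wKD. A general increase of jockey reads as the whole cause is argued against by jockey outside the place, whose log2 ratio of 0.5566 (SE 0.275; 0.60 and 0.52 within numbers) lay far below the 7.86 (SE 0.63) of the copy. The jockey copy was itself picked as the copy past the threshold, so a gap in this direction was partly fixed by that choice. The bound of this test was set after a first bound, of less than 0.5 outside the place, had been missed and after a test on the gypsy8 fragments had been dropped, because these were picked for their high reads, so a small rise across the family stays open. The jockey copy's smallest log2 ratio over 4 other scalings was 7.812 (SE 0.983). These scalings moved the median of all copies by -0.11 to 0.07, so none could have undone the rise. The value shows only that the rise did not rest on the scaling chosen. A variant that differs between the fly lines, such as an insertion or deletion, cannot be told apart from a local effect of the knockdown, because the lines differ wherever the knockdown does. A count of copies found in 1 genotype alone with a like neighbour within 10 kb does not decide this: it was 3, against at most 2 in 1000 shuffles, but 3 of these lie in the 42AB stretch and 0 at this place. A new source of small RNAs at this place in Ars2KD may therefore reflect the lines or the knockdown, and DNA sequence from both lines would separate these.

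HeT-A reads were lower in both Ars2KD libraries, past the threshold only under some alternatives. One copy as the whole source is argued against by -1.078, the higher log2 ratio of the 2 numbers without the copy that adds most. This holds only if reads of that copy were not counted at other copies, which could not be checked. The highest HeT-A value over 4 other scalings was -1.289 (SE 0.323). These scalings moved the median of all families by -0.14 to 0.009, too little to undo the fall. The value shows only that the fall did not rest on the scaling chosen. A smaller germline share of the tissue would lower germline transposons alike. Scaling within the repeat table centres most families near 0, so a shared loss would not show. The median of 32 germline-dominant families, 0.005184 (quartiles -0.241 to 0.245), therefore does not decide whether that share fell. On the same scale HeT-A had -1.30, with 0 of these families at or below it. A loss shared alike would not by itself give the HeT-A difference. Lower HeT-A small RNA across many telomeric copies in Ars2KD may be an effect of the knockdown, as a hypothesis found and tested on the same data, but fewer HeT-A copies at the telomeres of that fly line and reads shared between copies were not tested and stay open.

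The miRNA libraries split by number and not by knockdown, and 89 of 152 miRNAs differed more than 4-fold between the numbers (mean of both groups). Mature length as the basis is argued against by a Spearman rho of -0.05001 across miRNAs (r = -0.0474, permutation p = 0.543), which are not independent replicates. A few miRNAs taking most counts are argued against by a deviation correlation of 0.8734 without the 10 most abundant. A library batch, or a difference in stage or condition between the collections, is a candidate explanation, since the repeat families of the same libraries deviated together too (r = 0.6934). Despite more miRNA counts, fewer miRNA loci had a count in Ars2KD 2 and wKD 2 (151 and 185) than in Ars2KD 1 and wKD 1 (195 and 219). The 10 most abundant miRNAs held 93.4% and 84.7% of counts there, against 71.5% and 71.0%. What these differences reflect was not tested. No biological explanation was tested for this split.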
